A study of Homo sapiens with 80 samples.

How the data were processed

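The deposited table holds raw gene counts per library, made by the authors before deposit. According to the submitters' notes, adapters were trimmed with cutadapt 2.8 and reads were mapped with HISAT2 2.1.0 to the human genome GRCh38. The counting program, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here, so calls for antisense genes and close paralogs carry that uncertainty. The table has no ribosomal RNA genes.

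The table has 48477 genes, typed by the authors into 16 RNA classes. Chromosome Y genes and X-inactivation transcripts, 318 in all, were left out of all tests and tables, and 48159 were kept. Of the table's genes 46358 carry an Ensembl id, 46111 of which are in GENCODE 29, the source of the positions and gene spans used here, and 2119 have no Ensembl id. The latter are mainly small RNA families, such as the tRNA families, that the deposited table lists under a family name.

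All 80 labelled libraries in 10 groups were used. The table has 16 healthy PBMC and 16 healthy plasma columns where the labels give 13 of each, so 6 columns that match no label were left out of every step. No labelled library was removed. Depth is given per group at the start of the results and per library in the tables. Values are whole counts, and CPM values are counts scaled by the total and by the size factor of the main test. In plasma these size factors ran from 0.08 to 3.593, so CPM values there are not shares of a library.

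Groups, the tests of the 8 comparisons and the 30 gene lists were fixed before the data were examined, as were the alternatives, except measures, tests and alternatives said to have been added later and the list of genes that glucocorticoids induce. Each of the 8 comparisons was run in edgeR 4.0.16 with quasi-likelihood tests (robust estimation, TMM scaling, genes filtered by group size at a minimum count of 10), and p values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Frozen tumor and healthy tissue share patients, so the patient is a block in that fit. PBMC and plasma groups share 1 estimate of the spread per material. The difference between the plasma and the PBMC effect of IBC was fitted over 58 libraries with the donor as a block. Frozen pairs come from the patient numbers in the labels, and PBMC and plasma libraries were paired by the equal numbers in their labels. Deviations from the group mean correlated best with the own number in 2 of 4 frozen pairs, and between PBMCs and plasma in 3 of 13 healthy, 1 of 6 non-IBC and 0 of 10 IBC pairs, so the data show no pairing of PBMCs with plasma.

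The 30 gene lists were written from general knowledge of pathways and cell types. Lists with 5 or more tested members were ranked by camera in limma 3.58.1 with a preset correlation of 0.01, again with a correlation estimated from the data, and by fry, each adjusted over the lists of a comparison. Members were also adjusted over the list alone. Shares of RNA classes and genes detected at a common depth were compared by exact permutation, or by 100000 random permutations where both groups have 10 or more libraries. Frozen tissue was compared by flipping the 4 pairs, for which the smallest p is 0.125. Libraries were thinned to 18827854 counts in frozen tissue, 10851436 in FFPE tissue, 9150516 in PBMCs and 961613 in plasma before genes with 1 or more counts were counted.

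Genes are named by a rule set in advance: the 6 higher and 6 lower genes with the largest fold change among those that pass and lie at or above the median abundance, then up to 4 passing members of a described list or 2 where none passes. Pseudogenes, clone names, immunoglobulin and T cell receptor segments and HLA genes are outside the first part of the rule. Abundant small RNAs with fixed roles are named where tested. For a gene at 0 in a whole group the text gives a lower bound of the fold, with 3 counts set as a floor over that group.

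Alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE size factors, total counts only, no low-count filter, a minimum count of 50, protein-coding genes only, a 2-fold minimum, library total as covariate, replicate numbers as block or no block, only the groups compared, and each library left out in the frozen and FFPE sets and, added after the values were seen, in plasma. Groups were also split at random, 100 splits including the real one per comparison and 32 regroupings for frozen tissue, of which the real one and 7 others part all 4 patient pairs.

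The tests were tested on simulated data built from the same libraries, with 200 changed genes at folds of 2, 4 and 16. The changed genes were drawn from those above the median abundance, and no patient or batch effect was simulated. Recovery may therefore be lower for tested genes in general. In the main test 92.4% of 16-fold changes were recovered in frozen tissue, 71.2% in FFPE tissue, 98.5% in PBMCs and 15.2% in plasma for IBC against healthy donors, with 7, 5, 8 and 6 false calls. At 4-fold the values were 25.4, 32.8, 97 and 1.5%. The false calls are counted over all 3 folds and do not weigh alike. In plasma the 6 stood beside 0, 1 and 10 changed genes recovered at folds of 2, 4 and 16. In PBMCs the 8 stood beside 39, 65 and 65. False calls were therefore a larger part of the calls in plasma, and genes called there may hold more of them than the threshold implies. A simulated list of 30 genes, all raised 2-fold, had an adjusted p of 0.152 by fry in frozen tissue and 9.95e-09 by camera. In plasma against healthy donors camera gave 0.925 for IBC and 0.921 for non-IBC, and fry 0.268 and 0.698. A list that fails by fry in frozen tissue, or by either test in plasma, is therefore not shown to be unchanged. Camera with an estimated correlation was not run on simulated lists. No pair of libraries within a group looked like a copy of another, and pairs across groups were not compared. The scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.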

Results

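RNA was sequenced with TGIRT-seq, in which a thermostable group II intron reverse transcriptase copies coding RNA and structured non-coding RNA in the same reaction. The study covers inflammatory breast cancer (IBC), a rare and fast form of breast cancer marked by swollen, reddened skin, and sets it beside non-IBC breast cancer and healthy donors. In total 80 libraries fell into 10 groups. Frozen breast tumor and matched healthy breast tissue came from 4 patients, with 4 libraries of each. Formalin-fixed, paraffin-embedded (FFPE) tumors came from 10 IBC and 4 non-IBC patients. Peripheral blood mononuclear cells (PBMCs) and plasma were each taken from 13 healthy donors, 6 non-IBC patients and 10 IBC patients.

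Total gene counts per library (M stands for 1e6 counts) ranged from 30.92 to 46.15 M in frozen tumors and from 18.83 to 37.71 M in healthy breast. They ranged from 10.85 to 41.68 M in FFPE IBC tumors and from 23.32 to 39.37 M in FFPE non-IBC tumors. PBMC libraries held 9.15 to 44.61 M in healthy donors, 41.91 to 54.1 M in non-IBC patients and 33.29 to 45.19 M in IBC patients. Plasma was the shallowest material, with 0.96 to 5.27 M in healthy donors, 2.14 to 12.99 M in non-IBC patients and 3.69 to 18.18 M in IBC patients. Lower bounds of folds given below cover counting error only.

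**Figure D1:**
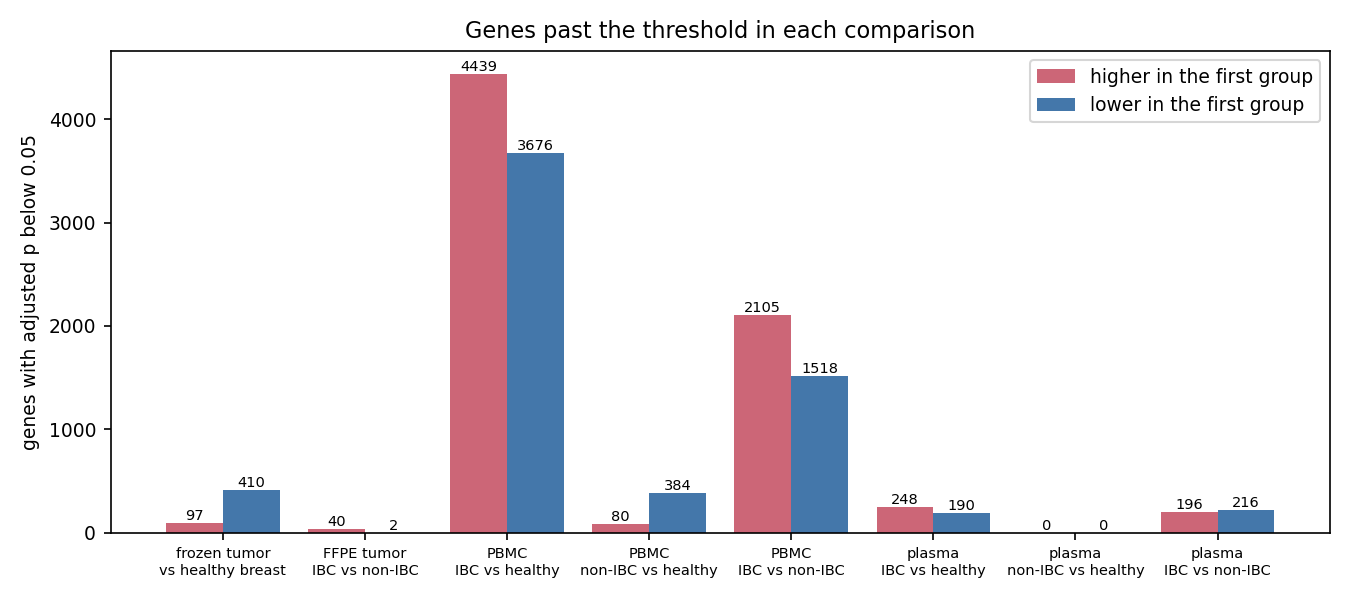
Bars give the number of genes with an adjusted p below 0.05 in each of the 8 comparisons, split into genes higher and genes lower in the group named before "vs". PBMCs of IBC patients against healthy donors gave the most genes, 4439 higher and 3676 lower, and plasma of non-IBC patients against healthy donors gave 0 and 0.

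Frozen tumors were compared with healthy tissue of the same patients to ask which transcripts mark the tumor. Some luminal epithelial, mitotic and histone transcripts were higher in the tumors and some of the basal and contractile layer of the breast lower, though no list held with an estimated correlation or by fry. Fry also missed a simulated list raised 2-fold in data of this size (adjusted p = 0.152). A list that fails by fry here is therefore not shown to be unchanged. S100A14, an epithelial calcium-binding gene, and AGR2, a protein-folding enzyme of secretory epithelium, stood among the largest gains. SOX10, a neural crest and basal progenitor factor, and GABRP, a GABA receptor subunit of basal cells, stood among the largest losses. Several small structured RNAs, above all transfer RNAs, were also lower in the tumors.

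Of 24200 genes tested, 97 were higher and 410 lower in tumor. The 6 largest gains by the naming rule were FOXJ1, the switch for motile cilia (log2 fold change 5.61), S100A14 (4.13), the histone H3 copies HIST2H3A (4.05) and HIST2H3C (3.83), AGR2 (3.95) and TTC39A (3.64). S100A14 rose from 5.94 ± 5.71 to 79.7 ± 22.0 CPM (SD, n = 4 each, edgeR adjusted p = 0.0252), with no overlap of the 2 ranges. CPM are counts scaled to 1e6 per library with its size factor applied. The 6 largest losses were the tyrosine tRNA family TRY-GTA (-9.61), the potassium channel gene KCNC2 (-8.82), SOX10 (-8.31), TAT (-7.79), the Schwann cell cadherin CDH19 (-7.57) and GABRP (-7.47). FOXJ1 ranged from 0 to 88.66 CPM over the 4 tumors, and without tumor library 2 its change in the unpaired fit was 1.45. SOX10 fell from 31.1 ± 13.2 to 0.106 ± 0.120 CPM (SD, n = 4 each, SE of the log2 change 0.93, edgeR adjusted p = 0.0112). HIST2H3A and HIST2H3C are near-identical copies, so the share of reads assigned to each is uncertain.

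By camera 23 of the 30 gene lists moved in frozen tumor, 0 of them with an estimated correlation and 0 by fry. Among proliferation genes 3 of 30 were higher, namely BIRC5 (3.65), the mitotic cyclin CCNB1 (2.70) and the spindle gene NUSAP1 (2.22), and 20 were higher when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Among replication-dependent histones 4 of 36 were higher, including HIST1H1B (2.92) and HIST1H2AM (2.82), and 28 when adjusted over the list alone (0.369). Luminal and estrogen response genes included 3 higher, with the keratins KRT19 (2.39) and KRT8 (2.07), and 8 when adjusted over the list alone (0.504). Basal and myoepithelial genes included 3 lower, the smooth muscle proteins MYH11 (-3.79) and CNN1 (-3.45) and the growth factor receptor EGFR (-3.96), with 12 lower and 1 higher when adjusted over the list alone (0.369). Of 8 tested neutrophil genes 2 were lower, MME (-3.89), which myoepithelial cells also express, and ALPL (-3.49), with 3 lower when adjusted over the list alone (0.369). EGR1, an immediate early transcription factor, fell by 3.41 on the log2 scale, and IER3, an inflammatory survival gene, rose by 3.19. With 0 genes passing, camera also called epithelial, matrix, interferon, hypoxia and antigen presentation genes upward and adipocyte, endothelial, platelet and hepatocyte genes downward.

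Of 11 spliceosomal small nuclear RNAs tested in frozen tumor 4 were lower, and all 11 when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). RNU12 (-3.64), RNU6 (-3.68), RNU11 (-3.31) and RNU5 (-2.83) passed. Mitochondrially encoded mRNAs included 1 lower, MT-CYB (-2.65), and 10 when adjusted over the list alone (0.504). Of 47 tRNA families 31 were lower, and of 322 small nucleolar RNAs 47 were lower. POLR2F, a subunit shared by the RNA polymerases, fell by 2.51, and ALK, from the list of genes reported in earlier IBC work, fell by 3.21. The span of POLR2F contains that of SOX10, which fell by 8.31, and how reads in overlapping genes were counted is not given. The fall of POLR2F therefore cannot be told apart from that of SOX10. Scaling by total counts moved the median of all genes by 0.37 and gave 292 higher and 342 lower genes, 46.1% higher against 19.1%. The count also rested on each patient: it was 195, 132, 0 and 96 without patients 1, 2, 3 and 4, and the 0 without patient 3 came from edgeR beside 3448 genes at an unadjusted p under 0.05.

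FFPE tumors of IBC patients were compared with those of non-IBC patients to ask what sets IBC tumor tissue apart. IBC tumors carried more of the immediate early transcripts that cells switch on within minutes of a stimulus, among them FOS, JUN and EGR1, which encode transcription factors, and DUSP1, which encodes a phosphatase that ends kinase signaling. They also carried more of ZBTB16, a zinc finger gene that steroid hormones induce, and of PER1, a core gene of the circadian clock. Many tRNA families rose with them.

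Of 27396 genes tested, 40 were higher and 2 lower in IBC tumors. The 6 largest gains by the naming rule were ZBTB16 (log2 fold change 5.09, SE 0.93, adjusted p = 0.0429), FOS (4.46, adjusted p = 0.0201), the lymphocyte signaling regulator RGS1 (3.92), the alanine tRNA family TRA-CGC (3.76), PER1 (3.55) and DUSP1 (3.54). ZBTB16 measured 947 ± 441 CPM in IBC (SD, n = 10) and 27.9 ± 27.4 in non-IBC tumors (SD, n = 4). The 2 lower genes, named here after their values were seen, were the non-coding RNA LINC01606 (-5.75) and a T cell receptor segment. In 5 of 21 immediate early genes the rise passed, with EGR1 at 3.41 (adjusted p = 0.00773) and JUN at 2.36 (adjusted p = 0.0147), and in 12 when adjusted over the list alone. This list held with an estimated correlation (adjusted p = 0.0266) and by fry (0.0157), and it was the only list of 10 called by camera to do so.

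The other lists that camera called in FFPE tumors did not hold with an estimated correlation. Spliceosomal small nuclear RNAs included 1 higher, RNU6 (1.59), and 6 when adjusted over the list alone (adjusted p = 0.345 with an estimated correlation). Mitochondrially encoded mRNAs included 1 higher, MT-ATP8 (3.01), and 7 when adjusted over the list alone (0.413). Basal and myoepithelial genes leaned upward with 0 passing and 3 when adjusted over the list alone (0.191), led by DST (1.40, adjusted p = 0.139) and KRT14 (3.46, adjusted p = 0.167). Fibroblast and matrix genes leaned upward with 0 passing and 5 when adjusted over the list alone (0.413), led by the collagens COL5A2 (1.57) and COL1A2 (1.76). Proliferation genes such as TOP2A (-2.06) and MCM4 (-1.52), the B cell gene MS4A1 (-2.91) and the epithelial genes CD24 (-2.43) and ESRP1 (-1.61) leaned downward, and none passed. The hepatocyte list, with 6 genes tested and a median of 2.77, was not called by camera (adjusted p = 0.422), and 0 of its genes passed, or 3 when adjusted over the list alone.

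Of 47 tRNA families 22 were higher in FFPE IBC tumors. The tRNA class held 5.12 ± 2.05% of gene counts in IBC (SD, n = 10) and 1.40 ± 0.51% in non-IBC tumors (n = 4), with an exact permutation p of 0.005 and an adjusted value of 0.0799 over the 16 classes. The count of 42 genes became 11 without non-IBC library 4, 1 without non-IBC library 6 and 15 without IBC library 7. With 4 non-IBC tumors the comparison is small.

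**Figure D2:**
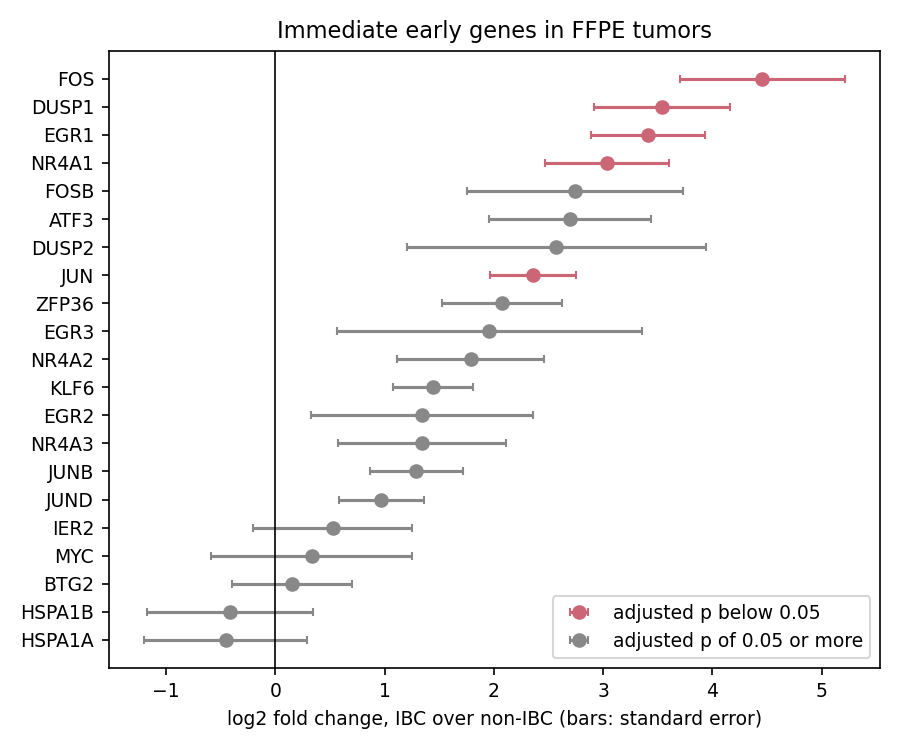
Points give the log2 fold change of each of the 21 immediate early genes between FFPE IBC (n = 10) and non-IBC tumors (n = 4), with the standard error from edgeR as bars. FOS has the largest rise, 4.46, and 5 genes pass an adjusted p of 0.05.

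PBMCs of IBC patients were compared with those of healthy donors to ask how blood cells differ in IBC. IBC PBMCs carried far more tRNA, and more mitochondrial tRNA, vault RNA and spliceosomal small nuclear RNA. Ribosomal protein mRNAs and antigen presentation genes, which load peptides onto class I molecules, were lower. Part of the transcripts typical of NK cells, B cells, monocytes and platelets were lower too. Of the lists that fell, only antigen presentation held with an estimated correlation. The share of protein-coding counts in genes over 200 kb was larger, 22.7% against 13.7% in healthy donors. The losses were not tested apart from this shift.

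Of 25264 genes tested, 4439 were higher and 3676 lower in IBC PBMCs. All 6 of the largest gains by the naming rule were tRNA families, TRI-AAT (8.36), TRT-AGT (8.10), TRT-CGT (8.05), TRI-TAT (7.98), TRH-GTG (7.72) and TRX-CAT (7.67). TRH-GTG, a histidine tRNA, measured 8228 ± 5461 CPM in IBC (SD, n = 10) and 39.0 ± 46.8 in healthy donors (SD, n = 13, adjusted p = 3.85e-14). All 47 tRNA families tested were higher, 20 of 22 mitochondrial tRNAs and all 4 vault RNAs, with VTRNA1-1 at 3.59 and the Y RNAs RNY4 and RNY5 at 2.15 and 1.91. The tRNA class took 5.81 ± 1.94% of counts in IBC and 0.157 ± 0.137% in healthy donors (permutation p = 1e-05, the smallest these permutations can give). Mitochondrial tRNA took 23.2 ± 4.07% and 4.42 ± 1.95% (permutation p = 1e-05).

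**Figure D3:**
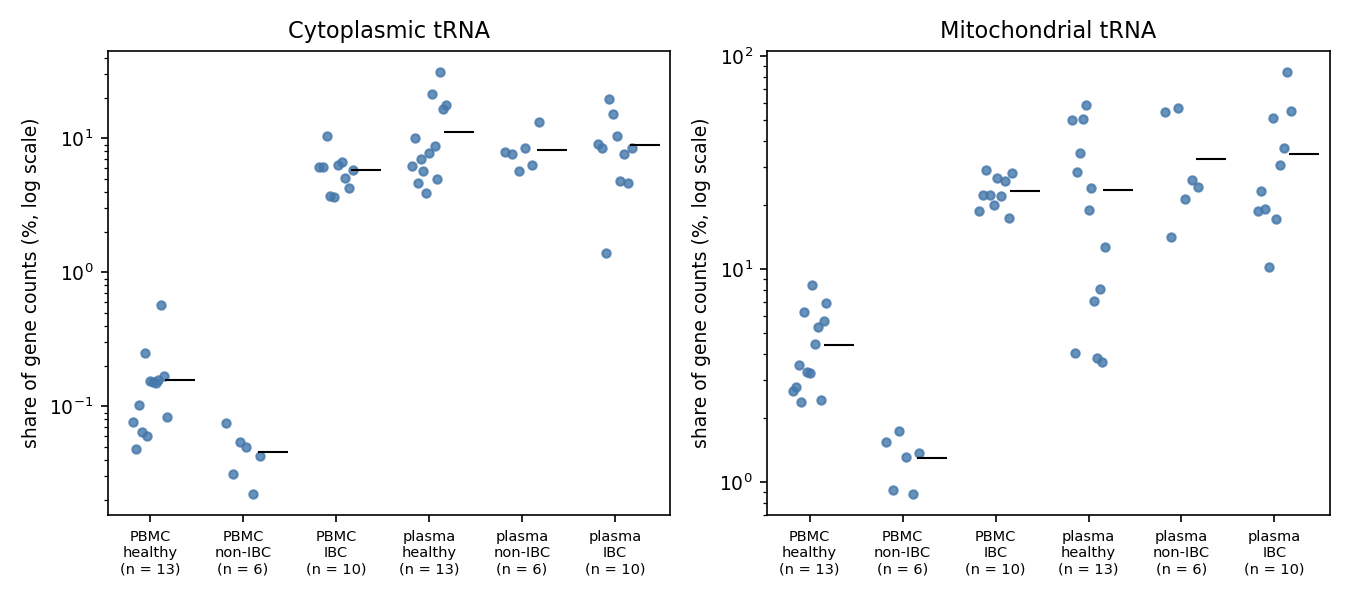
Points give the percent of gene counts in cytoplasmic and in mitochondrial tRNA for each PBMC and plasma library on a log axis, and bars beside them give group means. All 10 IBC PBMC libraries, from 3.68 to 10.4% tRNA, lie above all 19 other PBMC libraries.

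Spliceosomal small nuclear RNAs rose in 10 of 11 cases in IBC PBMCs (adjusted p = 0.0145 with an estimated correlation), among them RNU12 (1.99), RNU5 (1.69), RNU2 (1.59), RNU4 (1.53), RNU1 (1.59) and RNU6 (1.20). Antigen presentation genes fell in 12 of 15 cases (0.038), led by B2M (-1.45), PSMB9 (-1.27), PSMB8 (-1.21) and TAP1 (-1.18). B2M, the light chain of class I molecules, fell from 4498 ± 1309 to 1642 ± 348 CPM (SD, n = 13 and n = 10). Cytosolic ribosomal protein genes fell in 74 of 75 cases (0.581), with RPS10 at -1.55 and RPSA at -1.37. Spliceosome protein genes split into 6 higher and 24 lower (0.581), with SRSF4 at 0.94 and SF3B5 at -1.80, and MED13 (0.69) and GTF2F2 (1.10) of the RNA polymerase II machinery were higher. The counts adjusted over the list alone were 10, 12 and 74 for the small nuclear RNA, antigen presentation and ribosomal lists.

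Camera called several cell type lists downward in IBC PBMCs, each with an adjusted p of 0.581 or more with an estimated correlation. NK and cytotoxic genes fell in 8 of 16 cases (10 when adjusted over the list alone), with NKG7 at -1.69 and GZMA at -1.66. Plasma cell genes fell in 6 of 11, with IGHM at -1.91 and JCHAIN at -2.04, and monocyte genes fell in 8 of 19, with LYZ at -1.38 and S100A8 at -1.03. Platelet genes fell in 10 of 20, with PPBP at -1.31. B cell genes went both ways, 6 lower such as CD79B (-2.15) and TCL1A (-1.91) and 3 higher such as the scaffold gene BANK1 (1.09). T cell genes also went both ways, with CD3G (-1.62) and CD3D (-1.69) lower and THEMIS (1.07) higher, and the list as a whole did not pass. Replication-dependent histones fell in 15 of 36 (0.581), with HIST1H4H at -1.38 and HIST1H4E at -0.86. Mitochondrially encoded mRNAs rose in 8 of 13, with MT-ND6 at 3.48 and MT-ND5 at 2.69. Of the abundant RNA polymerase III transcripts 6 were higher and 2 lower, with RMRP at -1.02 and the signal recognition RNA RN7SL1 at -0.63 as the lower ones, and total counts turned the list median from 0.02 to -0.47. Proliferation genes fell in 5 of 30 cases (0.581) and genes of the HER2 amplicon in 3 of 7 (0.173).

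The 6 largest losses were CCL4L2 (-3.94), CCL3 (-3.67), CCL3L3 (-3.18), CCL4 (-2.93), SNORD28 (-2.22) and TNF (-2.20), 5 of them inflammatory cytokines. CCL3 ranged from 3.01 to 493 CPM in healthy donors and from 1.91 to 12.5 in IBC patients. Against only the 6 deeper healthy libraries CCL3 was 0.09, CCL3L3 0.83 and TNF 0.75 on the log2 scale, while CCL4L2 (-0.25) and CCL4 (-0.89) stayed lower and no longer passed, and the inflammatory list went from 1 higher and 5 lower to 8 higher and 1 lower. CCL3 and CCL3L3, and CCL4 and CCL4L2, are near-identical paralogs. Scaling by total counts moved the median of all genes by -0.52 and made 17.1% of 9778 changed genes higher, against 54.7% of 8115. Under it antisense genes flipped from 233 higher and 67 lower to 96 and 207.

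PBMCs of non-IBC patients were compared with those of healthy donors to ask whether breast cancer other than IBC leaves a trace in blood cells. Small non-coding RNAs were lower in these patients: small nucleolar RNAs, tRNAs, mitochondrial tRNAs and the minor spliceosome RNAs. The non-IBC libraries were deeper as a group, 41.91 to 54.1 M counts against 9.15 to 44.61 M in healthy donors. A batch that coincides with the diagnosis cannot be told apart from the disease in this comparison. The T helper coreceptor gene CD4 was higher, and ISG15, an interferon-induced modifier, was lower.

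Of 25264 genes tested, 80 were higher and 384 lower. The largest gains were the junction gene JUP (1.59), RPL28 (1.50), the T cell zinc finger gene TSHZ2 (1.48), FHIT (1.35), DLG2 (1.30) and QDPR (1.02). The largest losses were SNORD65 (-5.83), SNORD27 (-5.38), RNU6ATAC (-5.27), SNORD64 (-5.08), SNORD63 (-4.92) and the lymphocyte microRNA gene MIR150 (-4.86). RNU6ATAC, a minor spliceosome RNA, measured 12.4 ± 4.01 CPM in non-IBC patients (SD, n = 6) and 476 ± 475 in healthy donors (SD, n = 13, edgeR adjusted p = 0.000207). Lower were 216 of 339 small nucleolar RNAs, 34 of 47 tRNA families and all 22 mitochondrial tRNAs.

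Spliceosomal small nuclear RNAs fell in 6 of 11 cases and in 10 when adjusted over the list alone (adjusted p = 9.04e-05 with an estimated correlation), with RNU4ATAC at -3.82, RNU12 at -1.63 and RNU6 at -2.14. Abundant RNA polymerase III transcripts fell in 9 of 14, and in 12 when adjusted over the list alone (9.04e-05), with VTRNA1-1 at -2.57, RNase P RNA (RPPH1) at -1.60, RN7SL1 at -1.53 and RN7SL2 at -1.47. Ribosomal protein genes included 4 lower, such as RPL24 (-1.06) and RPS14 (-0.99), and 1 higher, RPL28, with 44 lower and 2 higher when adjusted over the list alone (0.434), while total counts gave 3 higher and 0 lower. Histones included 4 lower, such as HIST1H2BC (-1.27) and HIST1H2BG (-1.31), and 12 when adjusted over the list alone (0.373). ISG15 (-1.62), OSM (-3.11), B2M (-0.89) and S100A9 (-1.12) were lower and CD4 (0.89) higher, each the only changed gene of its list. Camera called 10 lists, of which these small nuclear RNA and RNA polymerase III lists held with an estimated correlation. Total counts moved the median of all genes by 0.46, so that 90.2% of 3530 changed genes were higher, against 17.2% of 464.

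PBMCs of IBC and non-IBC patients were compared to ask what separates IBC from other breast cancer in blood. The small structured RNAs that were lower in non-IBC patients and higher in IBC patients differed most. Some plasma cell transcripts, which encode antibody chains, and some antigen presentation genes were lower in IBC (8 of 11 and 7 of 15), though neither list held with an estimated correlation. The share of protein-coding counts in genes over 200 kb was larger in IBC, 22.7% against 17.1%. These losses were not tested apart from this shift.

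Of 25264 genes tested, 2105 were higher and 1518 lower in IBC. MIR126, an endothelial and platelet microRNA gene, was at 0 in all 6 non-IBC libraries and had counts in all 10 IBC libraries, at least 3280-fold higher against a floor of 3 counts over the group. The next largest gains were TRQ-CTG (10.67), MIR16 (10.52), TRH-GTG (10.43), TRA-CGC (10.41) and TRX-CAT (10.38). All 47 tRNA families, all 22 mitochondrial tRNAs and 222 of 339 small nucleolar RNAs were higher. The largest losses were the antibody joining chain JCHAIN (-2.88), IGLL5 (-2.47), CD180 (-2.29), the dendritic cell gene CD1C (-2.12), ITM2C (-2.04) and TXNDC5 (-2.04).

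All 11 spliceosomal small nuclear RNAs rose (adjusted p = 2.64e-06 with an estimated correlation), with RNU12 at 3.62, RNU6 at 3.35 and RNU2 at 2.75. Abundant RNA polymerase III transcripts rose in 10 of 14 cases and in 12 when adjusted over the list alone (0.00328), with VTRNA1-1 at 6.16 and RNY5 at 3.61. Plasma cell genes fell in 8 of 11 cases and in 10 when adjusted over the list alone (0.563), with IGHA1 at -3.59 and IGHM at -2.33. IGHA1 and JCHAIN were uneven among the 6 non-IBC libraries, from 12.16 to 513.7 and from 11.85 to 505.6 CPM, against at most 18.13 and 22.77 in IBC. B cell genes fell in 4 of 14, with CD79B at -1.79 and PAX5 at -1.31, and in 6 when adjusted over the list alone (0.757). Antigen presentation genes fell in 7 of 15 and in 12 when adjusted over the list alone (0.119), with TAPBP at -0.96, CD74 at -0.98 and CIITA at -1.12. The T cell genes CD4 (-1.22) and TRAC (-1.18), the splicing genes U2AF2 (-0.78) and PRPF8 (-0.81) and the ribosomal genes RPL15 (-1.13) and RPL28 (-1.23) were lower. The neutrophil gene VNN3 (2.23) and the prostaglandin synthase gene PTGS2 (3.50) were higher. Total counts moved the median of all genes by -0.94 and made 4.1% of 11717 changed genes higher, against 58.1% of 3623, while all 47 tRNA families stayed higher. Long intergenic RNAs flipped under it from 151 higher and 24 lower to 42 and 285.

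Plasma of IBC patients was compared with that of healthy donors to ask which circulating transcripts mark IBC. Some platelet and ribosomal protein transcripts were lower in IBC plasma, though neither list held with an estimated correlation. The share of protein-coding counts in genes over 200 kb was larger, 42.1% against 34.3% in healthy plasma. These losses were not tested apart from this shift. MPIG6B, TREML1 and GP9, which encode platelet surface proteins, had no counts in any IBC library. The gains included the interleukin receptor gene IL2RA and FCGR3B, a neutrophil antibody receptor, though most of the IL2RA signal lay in IBC library 4. The gains were not tested apart from the shift toward long genes either.

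Of 13345 genes tested, 248 were higher and 190 lower in IBC plasma, 438 in all, against 52 by limma voom and 9 when only the 2 groups were fitted. In simulated data of this comparison 6 false calls stood beside 0, 1 and 10 recovered changes of 2-fold, 4-fold and 16-fold. The 438 may therefore hold more false calls than the threshold implies. The count also moved with single libraries. It was 204, 270, 261, 259, 230, 276, 255, 258, 233, 247 and 289 without healthy libraries 2, 3, 4, 5, 6, 7, 9, 10, 11, 12 and 13, and 269 and 285 without IBC libraries 7 and 8. MPIG6B was at least 1300-fold lower than in healthy plasma, TREML1 918-fold, GP9 2040-fold, CAPNS1 1100-fold, MRFAP1 642-fold and ARMCX6 1190-fold, each against a floor of 3 counts over the 10 IBC libraries. MPIG6B and CAPNS1 had counts in 11 of 13 healthy libraries, TREML1 in 8, MRFAP1 in 7, and GP9 and ARMCX6 in 6. The largest gains were IL2RA (8.08), NUDT5 (7.88), APH1B (7.84), PRR14L (7.83), PSMG2 (7.79) and ATP6V1D (7.76). IL2RA measured 88.8 ± 252 CPM in IBC (SD, n = 10) and 0.308 ± 0.868 in healthy donors (SD, n = 13, adjusted p = 0.0212), and 4 IBC libraries had none of it. In IBC library 4 alone IL2RA, NUDT5, APH1B, PRR14L and ATP6V1D reached 803, 298.8, 758.6, 784.3 and 904 CPM, most of their IBC signal. Without that library 69 genes were higher and 235 lower, IL2RA was 5.02 and ATP6V1D 1.26 and neither passed, and NUDT5, APH1B and PRR14L fell below the count filter.

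By camera 5 lists moved in this comparison, and none held with an estimated correlation. Ribosomal protein genes fell in 5 of 75 cases, with RPL9 at -7.40, RPL35A at -6.61 and RPL37 at -5.39, and in 8 when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation). Platelet genes fell in 3 of 20 cases (0.185), also 3 when adjusted over the list alone. Histones fell in 2 of 20, HIST1H2BF (-8.20) and HIST1H1D (-7.06) (0.109). The erythroid list moved downward with 0 genes passing (0.274). Mitochondrially encoded mRNAs had a median of 1.01 yet were called downward by camera (0.547), and total counts turned the median to -0.77. Single members of other lists passed, NELFA (6.28) and CDK9 (-7.97) of transcript elongation, SRSF9 (-8.30), RNU4ATAC (-7.48), the neutrophil gene FCGR3B (5.77) and LCN2 (-8.89), a neutrophil iron carrier. NFKB2, of the inflammatory list, passed at an adjusted p of 0.0253, with no counts in the 10 IBC libraries and counts in 6 of 13 healthy libraries, at least 321-fold lower against a floor of 3 counts over the group. The median log2 change over all genes was 0.65, or 0.30 with total counts and 0.42 with RLE size factors, so a change near this size is no change relative to other genes. Total counts made 8.4% of 166 changed genes higher and RLE size factors 34.2% of 348, against 56.6% of 438.

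Plasma of non-IBC patients was compared with that of healthy donors to ask the same question for other breast cancer. The lean was toward more platelet, ribosomal, erythroid and histone transcripts, opposite to IBC, and no gene passed. The share of protein-coding counts in genes over 200 kb was lower, 24.1% against 34.3% in healthy plasma. The lean was not tested apart from this shift. By edgeR 0 of 13345 genes passed, 960 had an unadjusted p under 0.05, and DESeq2 and limma voom called 105 and 16. Camera called 9 lists upward and none held with an estimated correlation. They included ribosomal protein genes (0.102), with RPS29 at 2.75 (adjusted p = 0.38) and RPS19 at 2.11 (0.989), platelet genes (0.25), with ITGB3 at 3.13 (0.337) and SELP at 4.40 (0.398), and erythroid genes (0.119), with HBD at 3.35 (0.353) and HBA2 at 2.00 (0.388). Histones (0.119), with HIST1H2BK at 3.49 (0.508), and RNA polymerase III transcripts (0.355), with RN7SL1 at 2.64 (0.335) and RNY1 at 2.05 (0.335), leaned the same way, as did spliceosome protein, mitochondrial mRNA and antigen presentation genes (0.355 each) and hypoxia genes (0.102). Total counts turned the median of the mitochondrial mRNA list from 1.40 to -0.08. The median of all genes was -0.28, or -0.90 with total counts and 0.07 with RLE size factors. In simulated data of this size edgeR recovered 9.4% of 16-fold changes with 2 false calls and DESeq2 39.1% with 130, so a count of 0 does not exclude large changes.

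Plasma of IBC and non-IBC patients was compared to ask what separates the cancers in circulation. Platelet, ribosomal protein, histone and erythroid transcripts were lower in IBC plasma as lists. RN7SL1, the RNA of the signal recognition particle, was lower too. These losses coincide with a larger share of counts in genes over 200 kb, 42.1% in IBC against 24.1% in non-IBC plasma.

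Of 13345 genes tested, 196 were higher and 216 lower in IBC, 412 in all, against 18 when only the 2 groups were fitted. The total was 221, 271, 96, 192, 239 and 258 without non-IBC libraries 1, 2, 3, 4, 5 and 6, with 13 to 55 genes higher. Against a floor of 3 counts over the 10 IBC libraries, MPIG6B was at least 5030-fold lower than in non-IBC plasma, TREML1 4310-fold, the tubulin gene TUBB4B 2070-fold, GUK1 1960-fold, GP9 1930-fold and CMTM5 1680-fold. TUBB4B had counts in all 6 non-IBC libraries, TREML1, GUK1 and CMTM5 in 5, and MPIG6B and GP9 in 4. Against the same floor over the 6 non-IBC libraries, SCARNA4 was at least 359-fold higher in IBC, SPEG 224-fold, SERPINI1 215-fold, PLA2G5 211-fold, EYA1 201-fold and the kinetochore gene NDC80 169-fold. These 6 had counts in 3 to 7 of 10 IBC libraries, and COL1A2 and CD8B, at least 134-fold and 299-fold higher, in 5 and 7. Most of the IBC signal of SPEG, SERPINI1, PLA2G5, EYA1, NDC80 and COL1A2 lay in IBC library 4, with 1240, 1079, 932.4, 1137, 937.2 and 753.8 CPM. That of SCARNA4 lay in library 9 (1342) and that of CD8B in library 6 (568.1). These CPM include the size factors: the whole scaRNA class took 0.0108% of the counts of library 9. Without library 4 the numbers were 70 higher and 241 lower, SCARNA4, SPEG, SERPINI1 and EYA1 no longer passed, and PLA2G5, NDC80 and COL1A2 fell below the count filter. SCARNA4 without library 9 and CD8B without library 6 did not pass either. Of 20 platelet genes 5 were lower, with ITGB3 at -5.66, and 11 when adjusted over the list alone (adjusted p = 0.0366 with an estimated correlation). Of 75 ribosomal protein genes 7 were lower, with RPL9 at -8.38, RPL35A at -7.90 and RPL38 at -7.53, and 10 when adjusted over the list alone (0.00844). Histones (3 of 20, with HIST1H2BF at -8.89, and 6 when adjusted over the list alone) and erythroid genes (2 of 15, with HBB at -2.94 and HBD at -5.15) also held with an estimated correlation (0.0123 and 0.0317). The other 5 of the 9 lists camera called, all downward, did not hold: RNA polymerase III transcripts, spliceosome proteins and antigen presentation (0.221 each), mitochondrial mRNAs (0.207) and hypoxia (0.0738). RN7SL1 (-2.96), SRSF9 (-8.96), HNRNPC (-5.93) and LCN2 (-10.36) were lower. NFKB2, at 0 in all 10 IBC libraries, was at least 316-fold lower against the same floor over them, and it did not pass without non-IBC library 4. The median of all genes was 0.97, or 1.26 with total counts and 0.36 with RLE size factors, and RLE made 17.4% of 321 changed genes higher, against 47.6% of 412. LCN2, in this comparison and against healthy donors, was named after its values were seen.

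Protein-coding counts in genes spanning over 200 kb, a measure added after the data were seen, differed between plasma groups. They made up 42.1 ± 5.40% in IBC (SD, n = 10), 34.3 ± 7.66% in healthy donors (n = 13) and 24.1 ± 7.59% in non-IBC patients (n = 6). Counts spread evenly over the spans of all protein-coding genes would give 45.4%. The permutation p was 0.0116 for IBC against healthy donors (0.0185 adjusted), and exact permutation gave 0.000375 for IBC against non-IBC patients (0.00112 adjusted). For non-IBC patients against healthy donors exact permutation gave 0.0157 (0.0425 adjusted). In PBMCs the share was 22.7 ± 2.46% in IBC, 13.7 ± 2.11% in healthy donors and 17.1 ± 1.47% in non-IBC patients (permutation p = 1e-05 for IBC against healthy donors).

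**Figure D4:**
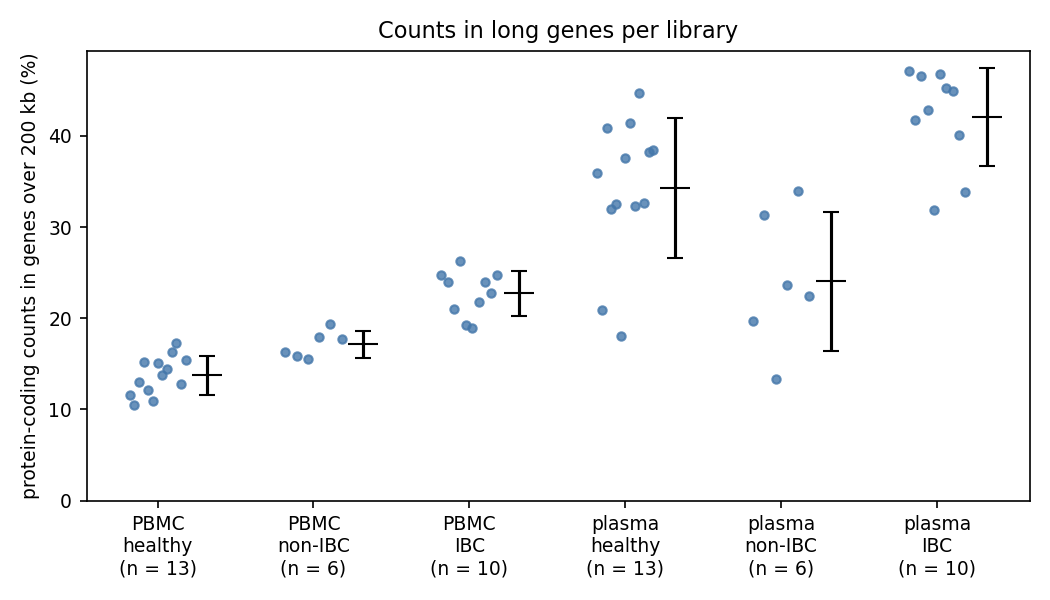
Points give the percent of protein-coding counts in genes over 200 kb for each PBMC and plasma library, with the group mean and SD beside them. IBC plasma has the highest group mean, 42.1%, and healthy PBMCs the lowest, 13.7%.

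The classes of RNA also shifted as shares of all gene counts. In PBMCs 12 of 16 classes differed between IBC and healthy donors, 10 between non-IBC and healthy donors and 15 between IBC and non-IBC patients. Protein-coding genes took 45.6 ± 6.15% of counts in IBC PBMCs, 57.2 ± 10.7% in healthy and 78.0 ± 3.17% in non-IBC PBMCs. In plasma 4 classes were lower in IBC than in healthy donors: 7SK, the 7SL RNAs, long intergenic RNAs and small nucleolar RNAs, and 0 passed when mitochondrial RNA and the 3 genes named at the end of this paragraph were left out of the total. The 7SL share was 1.22 ± 0.88% in IBC (SD, n = 10), 3.47 ± 2.85% in healthy donors (n = 13, permutation p = 0.00636) and 5.98 ± 1.08% in non-IBC plasma. Between IBC and non-IBC plasma 7 classes differed, and 0 did in the remaining plasma, FFPE and frozen comparisons. The 4 frozen pairs are too few for this test to pass. Most of the long intergenic counts of healthy and non-IBC plasma lay in 3 genes that overlap ribosomal RNA genes on chromosome 21, which took 4.80% of counts in IBC, 16.97% in healthy and 19.5% in non-IBC plasma. Without these and mitochondrial RNA the long intergenic share was not lower in IBC: 8.99 ± 3.34% against 7.28 ± 3.13% in healthy donors (SD, n = 10 and n = 13, permutation p = 0.218). Against non-IBC patients it turned higher (4.21 ± 2.46%, n = 6, exact permutation p = 0.0117, 0.0352 adjusted).

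After thinning to a common depth, non-IBC PBMCs showed 3051 more detected genes than healthy PBMCs, 27720 ± 717 (SD, n = 6) against 24670 ± 2207 (n = 13, exact permutation p = 0.00479). The difference was 1337 when 5 or more counts were asked for and 627 with protein-coding genes only, both past the threshold. The other 7 differences did not pass. They were 450 for frozen tumor against healthy tissue, 1473 for FFPE IBC against non-IBC tumors, 212 for IBC against healthy PBMCs and -2839 for IBC against non-IBC PBMCs. In plasma they were -965, -896 and -70 for IBC against healthy, non-IBC against healthy and IBC against non-IBC.

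The effect of IBC against healthy donors was compared between plasma and PBMCs, with equal numbers in a group taken as the same donor, which the libraries themselves did not show. Of 24249 genes tested, 5 had a more positive effect in plasma and 106 a more negative one, against 1728 and 2590 with no donor block. Of 47 tRNA families 36 were among the 106, with TRH-GTG at a difference of -7.37 (SE 1.09, adjusted p = 3e-04), and in the separate fits of each material it changed by 7.72 in PBMCs and 1.64 in plasma. The median difference over all genes was -0.68. In simulated data the test with donors as block recovered 0% of 4-fold, 3% of 16-fold and 15.2% of 64-fold differences. Genes that did not pass are therefore not shown to respond alike in both materials. The list of genes reported in earlier IBC work was called by camera in 0 of the 8 comparisons.

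**Figure D5:**
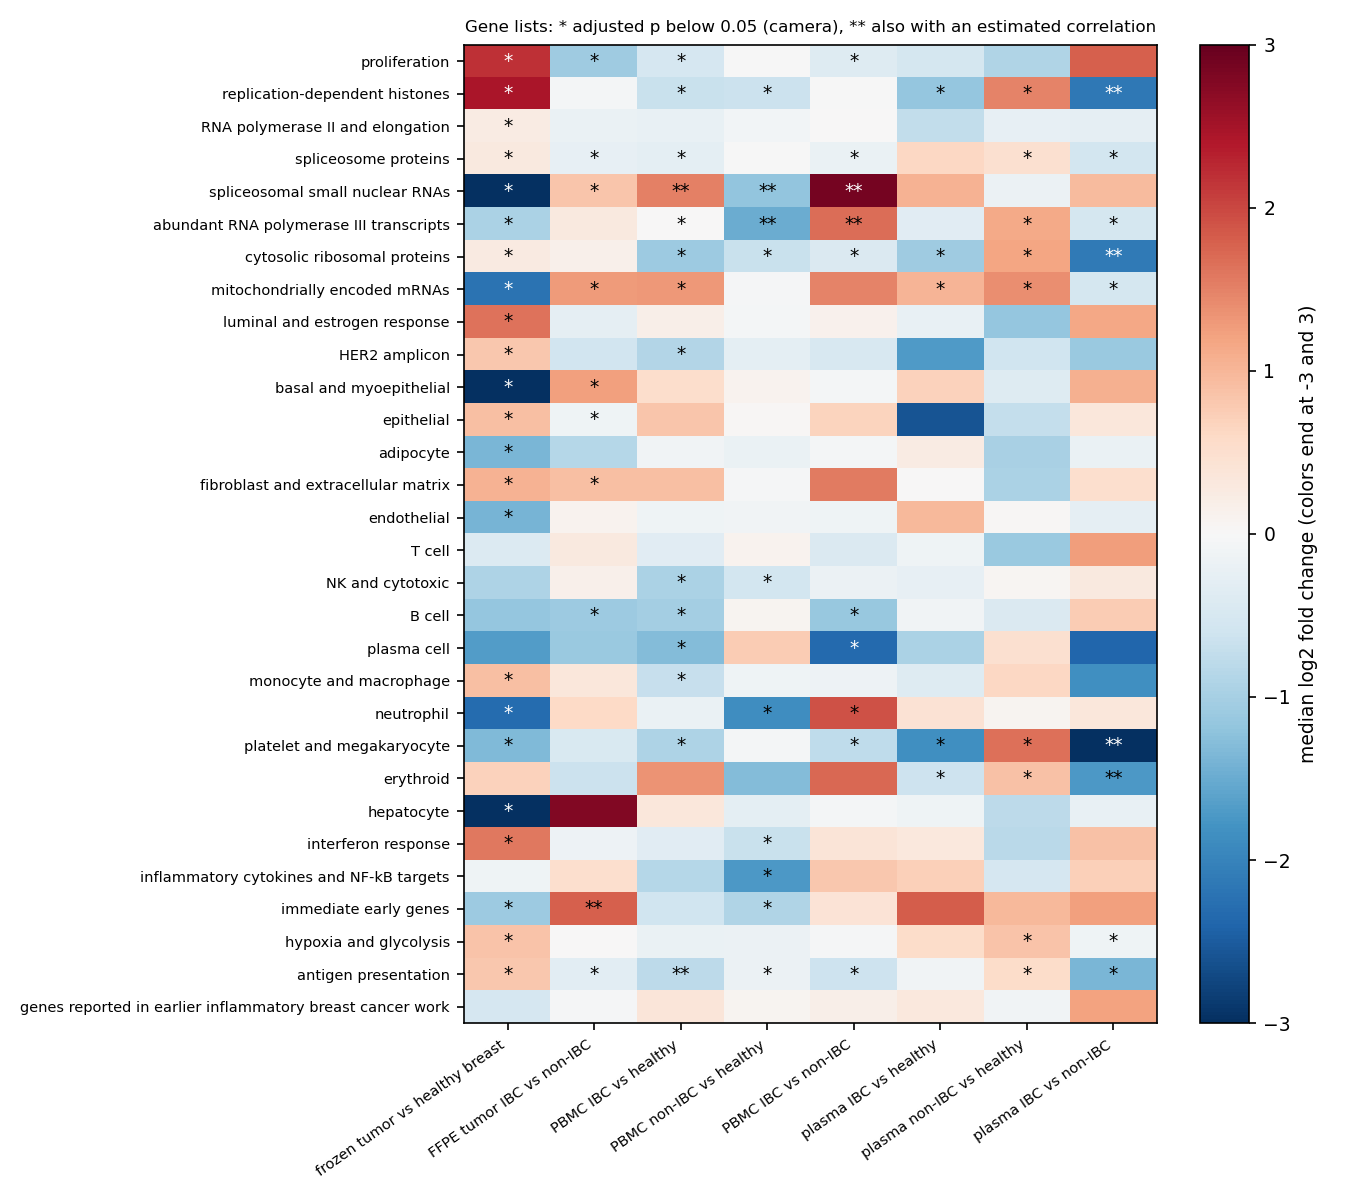
Colors give the median log2 fold change of each of the 30 gene lists in the 8 comparisons. An asterisk marks lists called by camera, and a double asterisk those that also passed with an estimated correlation, such as immediate early genes in FFPE tumors (median 1.79).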

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

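The patterns below were chosen after the results were seen, and so were the tests of depth and batch in PBMCs and the test within donors. All the other tests had their outcomes written down before they were run.

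The tRNAs, mitochondrial tRNAs, vault RNAs and spliceosomal small nuclear RNAs were higher in IBC PBMCs than in both other groups. Other structured RNAs went both ways: against healthy donors the Y RNAs RNY4 and RNY5 were higher, as given above. The shares of small nucleolar RNAs (13.0 against 22.2%), 7SL RNAs (2.90 against 5.59%) and 7SK (0.748 against 1.40%) were lower. All 47 tRNA families rose against healthy donors, and the tRNA share of every IBC library lay above the range of the other groups, with 0 IBC libraries inside it. A gain set by RNA length alone would lift small nucleolar RNAs under 100 nt over those of 120 nt or more. The smaller of the 2 differences was -1 on the log2 scale, so no such gain was seen within this class. The share of this class was itself lower against healthy donors, and tRNAs, vault RNAs and 7SL RNAs were not in the test. A length effect across classes therefore stays open. Depth is argued against, since the deepest group, non-IBC, had a median tRNA share of 0.0462%. A preparation or collection batch that coincides with the diagnosis cannot be told apart from the disease, and a true rise of tRNA in IBC blood cells stays open. Such a batch cannot be told apart for the lower small RNAs of non-IBC PBMCs either.

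Counts in long genes took a larger share in IBC plasma. Genes of silent families, such as olfactory receptors, should have few counts per kb in RNA, yet in IBC plasma the median of their density over that of all protein-coding genes was 1.14 (range 0.693 to 1.584). It was 0.862 in healthy plasma (0.128 to 1.335) and 0.6251 in non-IBC plasma (0.251 to 0.839), so the ranges overlap. Fragments of genomic DNA would give this, so they may be present in plasma of all 3 groups. The ratio was higher in IBC than in healthy donors (permutation p = 0.01854), so they may be present there to a greater degree. Healthy libraries were uneven: the deeper libraries 1 to 6 ran from 0.128 to 1.05 and libraries 7 to 13 from 0.489 to 1.34. IBC was not compared with these sets separately. The rise in IBC is not particular to plasma: in PBMCs the mean ratio was 0.374 in IBC, 0.145 in healthy donors and 0.250 in non-IBC patients. Against healthy donors the permutation p was 1e-05, the smallest these permutations can give, and against non-IBC patients the exact permutation p was 0.00787. The lower ribosomal protein, platelet, histone and erythroid lists of IBC against non-IBC plasma coincide with this shift and were not tested apart from it. The ratio differed there too (exact permutation p = 0.00175). Losses in IBC against healthy donors, in plasma and in PBMCs, were not tested apart from the shift either. The same holds for the gains in IBC plasma and for the losses in IBC against non-IBC PBMCs. Depth is argued against by a rank correlation of -0.37 within groups, and a few abundant genes are argued against by a permutation p of 0.01666 once 3 gene lists were removed. Whether IBC plasma holds more DNA or less RNA stays open, as does a difference in how plasma was drawn.

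Immediate early genes and tRNAs were higher in FFPE IBC tumors. Without the 3 IBC libraries with the fewest detected genes 0 of the 27 genes passed, 0 immediate early genes and 0 tRNAs, with a smallest adjusted p of 0.095. Their median log2 change was 2.49 (quartiles 2.23 and 3.00) against 2.63 (2.30 and 2.96), and 100% had at least 0.5 of their former change, so the calls ended through the p values and not the folds. This argues against these libraries as the source of the folds. A length effect is undecided, with a difference of 0.57 between short and long small nucleolar RNAs. Genes that glucocorticoids induce, without those already called, had a median of 1.15, so steroid treatment or stress of the patient could be a cause beside time from surgery to fixation. Treatment and handling are not in the labels, and the biological reading stays open.

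Chance as an explanation was tested by regrouping the same libraries at random. For frozen tissue 1 of 32 splits gave as many genes as the real 507, the highest other being 0. Only the real one and 7 of these splits part all 4 patient pairs, too few for a share under 0.05, and the rest set both libraries of some patients in 1 group. For FFPE tumors 2 of 100 splits did, 42 against a highest other of 143. For PBMCs 1 of 100 splits did for IBC against healthy donors (8115, highest other 2077), 3 for non-IBC against healthy donors (464, highest other 1052) and 1 for IBC against non-IBC (3623, highest other 720). For plasma 2 of 100 splits did for IBC against healthy donors (438, highest other 917) and 2 for IBC against non-IBC (412, highest other 523). These counts make chance an unlikely source for the FFPE, PBMC and these plasma comparisons. In FFPE tumors a split with 143 genes, several times the real count, points to a structure among the samples, and what the libraries of that split share was not examined. Single splits also called more than the real one with 1052, 917 and 523 genes. For plasma of non-IBC patients against healthy donors 100 of 100 splits gave as many as the real 0, the highest other being 1. No split can give fewer than 0, so this says nothing on chance.

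The effect of IBC differed between plasma and PBMCs in 111 genes by a direct test of the difference. That fit, with donors as block, was not split. Without donors as block 6 of 100 splits gave as many as the real 4318, the highest other being 4622, so chance cannot be excluded for that fit. A test within donors gave 208 genes, 77 of them among the 111, and 1 of 100 splits gave as many as the real 208, the highest other being 106. This makes chance unlikely for the 208 and leaves the 111 untested, and both rest on equal numbers marking the same donor. The tRNA families make up 36 of the 111 and all 47 families rose in PBMCs.

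A gap test for libraries far from the rest of their group marked 5 of 64 group measures, and chance flags about 1 in 20 groups. It covered groups of 4 to 10 libraries, so healthy PBMCs and healthy plasma, with 13 each, were not tested. The snRNA share of FFPE IBC library 10 was 1.906%, with the next library at 3.305%. The tRNA share of PBMC IBC library 3 was 10.36%, with the next at 6.67%, and that of healthy breast library 4 was 19.06%, with the next at 8.573%. In non-IBC plasma library 6 the tRNA share was 13.24%, with the next at 8.506%, and the snoRNA share 0.9931%, with the next at 0.3951%. In the untested groups, healthy plasma library 2 held 4.62% snRNA, with the next at 1.80%. Healthy PBMC library 11 held 0.57% tRNA, with the next at 0.251%. None of these libraries was removed.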

How the results depend on the processing

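All settings below were planned before the data were examined except those said to have been added after the values were seen. Unless a cause is given, the cause was not tested.

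With DESeq2 the number of changed genes was 3845 instead of 507 in frozen tissue, 421 instead of 42 in FFPE tumors and 807 instead of 464 for non-IBC against healthy PBMCs. In plasma it was 806 instead of 438 for IBC against healthy donors, 105 instead of 0 for non-IBC against healthy donors and 997 instead of 412 for IBC against non-IBC. With limma voom the numbers were 789 in frozen tissue, 6 in FFPE tumors, 1828 for non-IBC against healthy PBMCs and 8803 instead of 3623 for IBC against non-IBC PBMCs. In plasma voom gave 52, 16 and 733 in the same order.

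Scaling by total counts only gave 3530 genes for non-IBC against healthy PBMCs, 11717 for IBC against non-IBC PBMCs and 166 for IBC against healthy plasma. Total counts are shared with the small RNAs that fill IBC PBMC libraries, so other genes move downward there by construction. RLE size factors kept every number within a factor of 1.5.

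Without the low-count filter the numbers were 1711 in frozen tissue and 8909, 1439 and 3680 in plasma. A minimum count of 50 gave 127 for IBC against healthy plasma and 194 for IBC against non-IBC plasma, with fewer genes tested. Protein-coding genes alone gave 9 in FFPE tumors, 18 for non-IBC against healthy PBMCs and 218 for IBC against healthy plasma, since small RNAs were left out. A 2-fold minimum gave 4103 instead of 8115 for IBC against healthy PBMCs and 1724 for IBC against non-IBC PBMCs, by construction. With library total as covariate the numbers were 222 in frozen tissue, 806 for IBC against healthy plasma and 664 for IBC against non-IBC plasma.

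Frozen tissue with no replicate block gave 892 genes. With the replicate block, which pairs unrelated people by number in the other sets, the numbers were 0 in FFPE tumors, 892 for non-IBC against healthy PBMCs, 22 for IBC against healthy plasma and 152 for IBC against non-IBC plasma. The difference between plasma and PBMCs gave 4318 genes with no replicate block instead of 111. Leaving out 1 patient or library gave 0 to 1224 genes in frozen tissue, the lowest without patient 3 and the highest without tumor library 1 in the unpaired fit. It gave 1 to 57 in FFPE tumors, and smaller groups leave less power. In plasma, where leaving out was added after the values were seen, it gave 204 (healthy library 2) to 510 (IBC library 3) for IBC against healthy donors and 96 (non-IBC library 3) to 562 (IBC library 10) for IBC against non-IBC. Fitting only the groups compared gave 9 for IBC against healthy plasma and 18 for IBC against non-IBC plasma, with fewer libraries for the spread.

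With an estimated correlation the number of lists changed from 23 to 0 in frozen tissue and from 10 to 1 in FFPE tumors. In PBMCs it changed from 14, 10 and 10 to 2, 2 and 2, and in plasma from 5, 9 and 9 to 0, 0 and 4. By fry it was 0 in frozen tissue, 1 in FFPE tumors, 2 for non-IBC against healthy PBMCs and 2, 0 and 5 in plasma.

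The number of RNA classes with another share became 1 instead of 0 in FFPE tumors and 3 instead of 7 for IBC against non-IBC plasma on a log scale. It became 9 instead of 15 for IBC against non-IBC PBMCs with medians. Without mitochondrial RNA and the 3 long intergenic genes at the ribosomal RNA locus it became 0 instead of 4 for IBC against healthy plasma and 1 instead of 0 for non-IBC against healthy plasma.

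Genes detected at a common depth changed sign when 5 or more counts were asked for: -655 instead of 450 in frozen tissue, -218 instead of 1473 in FFPE tumors, -694 instead of 212 for IBC against healthy PBMCs and 632 instead of -70 for IBC against non-IBC plasma. For IBC against non-IBC PBMCs the same setting gave -2031 instead of -2839, past the threshold that the main setting missed. With protein-coding genes only the difference was -393 in frozen tissue and -115 in FFPE tumors.

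Added after the values were seen: FFPE tumors without the 3 IBC libraries with the fewest detected genes gave 1 gene. Only the 7 shallower healthy libraries gave 4597 for IBC against healthy PBMCs, only the 6 deeper ones gave 1625 for non-IBC against healthy PBMCs, and leaving out the short RNA classes gave 33 there. For IBC against healthy plasma 206 genes were left without IBC library 9 and healthy library 2, and 177 without libraries under 0.25 of the median total. The difference between plasma and PBMCs gave 531 genes with voom and a donor correlation, which was planned, and 208 with limma on the difference within donors, which was added.

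Of the 222 genes named in a comparison, 5 changed sign in some setting. Against the 6 deeper healthy libraries CCL3 was 0.09, CCL3L3 0.83 and TNF 0.75, and with library total as covariate CCL3L3 was 0.73, TNF 0.66 and, for non-IBC against healthy PBMCs, OSM 0.63. With the replicate block ATP6V1D was -0.03 in IBC against healthy plasma. Over all settings 3752 of 4495 values kept side and call, 726 were weaker and 10 stronger.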

Other observations

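The observations here were chosen after the results were seen, and no test was added for them. In frozen tumors EGR1 was lower than in healthy tissue of the same patients, with no overlap of the ranges, 15.37 to 25.29 against 163.5 to 281.4 CPM. In FFPE tumors EGR1 was higher in IBC than in non-IBC, 149.2 against 14.02. EGR1 marks cells under growth or stress signals, and handling of the tissue is known to induce it.

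Genes typical of T cells and of B cells moved in both directions in IBC PBMCs. The short T cell genes CD3D and CD3G were lower while THEMIS, a long gene that sets the signal threshold of T cells, was higher. In B cells CD79B and TCL1A were lower while the long gene BANK1 was higher. The members of these lists were not tallied by gene length, so a link with length was not tested. Protein-coding counts in genes over 200 kb rose from 13.73% in healthy to 22.73% in IBC PBMCs. The share of lymphocytes therefore cannot be read from single marker genes here.

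MIR126 had no counts in 6 of 6 non-IBC PBMC libraries and had counts in 10 of 10 IBC libraries. MIR16 was higher by 10.52 on the log2 scale in the same comparison, and MIR150, a lymphocyte microRNA gene, was lower by 4.86 in non-IBC than in healthy PBMCs. The direction is that of the tRNAs in both comparisons. Both use the same 6 non-IBC libraries, so they are not independent of each other.

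In plasma 3 platelet surface genes, MPIG6B, TREML1 and GP9, had no counts in any of the 10 IBC libraries although their median total, 8.255 M, exceeded that of healthy donors, 2.31 M (M stands for 1e6 counts). Not all healthy libraries had them either: MPIG6B had counts in 11 of 13, TREML1 in 8 and GP9 in 6. Leftover platelets in plasma depend on how blood was spun, so a lower platelet count in the tube is open beside a lower release of platelet RNA in IBC. Mitochondrial tRNA took 34.62% of counts in IBC, 23.48% in healthy and 32.98% in non-IBC plasma. Of 22 mitochondrial tRNAs 8 were higher in IBC than in healthy plasma. The ranges overlapped, 10.2 to 84.1% in IBC and 3.67 to 59.1% in healthy plasma, and the class share did not pass. Healthy libraries 1, 3, 4, 5 and 6 held 28.5 to 59.1%, library 2 held 4.02%, and libraries 7 to 13 held 3.67 to 24.1%.

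Data that would settle open points include the dates of library preparation, the treatment of patients before sampling, the time from surgery to fixation and the protocol of plasma collection. Plasma digested with DNase before library preparation would part DNA from RNA fragments.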
